A study of Mus musculus with 3 samples.

How the data were processed

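Dorsal skin of male C57BL/6 mice was profiled with droplet-based 3' single-cell sequencing, per the labels, in 3 libraries: non-lesional skin, wound bed at day 2 and wound bed at day 7. Per the labels, tissue was digested with collagenase D and DNase1 and reads were aligned to mm10 with Cell Ranger 3.0.2, followed by Seurat 3.0. Per the file headers, the deposited tables were written by Cell Ranger 5.0.0, and this difference was not resolved. The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger and restricted to barcodes called as cells. The method of cell calling is not given in the sources used here. Of 27998 gene identifiers, 27624 were found in GENCODE M21 on GRCm38, from which positions (1-based) were taken.

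Library totals were 123088680, 138046172 and 102345327 UMIs for non-lesional skin, day 2 and day 7. Barcodes were kept with at least 200 genes detected and at most 10% of UMIs from mitochondrial genes. These limits removed 192, 390 and 543 barcodes for genes and 368, 372 and 1632 for mitochondrial UMIs. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and the top 0.8% per 1000 barcodes were removed, 943, 606 and 428 barcodes. The score's own threshold would have marked 445, 2 and 1. This left 86.5%, 84.6% and 65.2% of barcodes.

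Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 with seed 0, without integration across libraries. The 37 clusters were given classes from 16 fixed marker lists with a minimum score of 1.5, and are called "-like" because the marker genes define them. Clusters stayed unnamed if they were under that score, far under the class's highest score, or had too few of its markers detected. Shallow clusters with no marker among their leading genes also stayed unnamed, as did those whose leading genes belonged to another list. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.

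UMIs of each gene were summed per class and library and expressed as CPM. Log2 folds used a pseudocount of 5 CPM. Ratios carry exact conditional binomial 95% intervals, shares of cells Clopper-Pearson intervals and single sums Poisson intervals. A class was compared where both libraries held at least 50 of its cells. A gene with 0 UMIs in one library was given as a bound against a floor of 3 counts over the class, and a share of 0 with the limit of 3 cells over the library, which is lower than the upper end of a Clopper-Pearson interval. For each of 29 fixed gene lists the median log2 fold over members with at least 10 UMIs in the pair was placed among 10000 random lists matched in 20 expression bins, as a description and not as a test. Shares of cells with a UMI were also taken after thinning cells to 1000 UMIs, with shallower cells left out: 1231 of 2040 day 2 neutrophil-like cells, 63 of 178 day 2 T, NK or innate lymphoid-like cells and 57 of 4103 day 2 fibroblast-like cells. Thinned shares of these classes therefore describe their deeper cells. The part of a level that free RNA brings to day 2 fibroblast-like cells was the highest share at which 3 neutrophil and 3 macrophage genes stood there, times the level in those classes. Its use was chosen after the results were seen. With 1 library per group no test between groups was made. The thresholds, lists, classes and alternatives were chosen before the data were examined, except where stated.

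Genes were named by a fixed rule. A gene needed at least 50 CPM in the higher library, a UMI in at least 10% of its cells, at least 0.2 of the highest level in any other class, and a fold of at least 2, and mitochondrial, ribosomal, haemoglobin and unnamed predicted genes were excluded. Among these the genes with the largest log2 folds in each direction were named, 12 per pair in fibroblast-like cells, 8 in monocyte- or macrophage-like cells and 5 in other classes. To them were added the 4 members with the largest log2 fold of each list, and Il1a, Il1b, Il1r1, Il1rn, Pparg, Adipoq, Dlk1, Axin2, Lef1, Sfrp2, Dkk2, Wnt5a, Camp and Pdgfra. The levels of Il6, Lpl and Col1a1 drawn for fibroblast-like cells, and the choice of genes given with identifier and position, were made after their values were seen. Without the limit on other classes, 22 of the 24 genes of fibroblast-like cells at day 2 were the same.

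The procedure was tested on simulated data, with counts of fibroblast-like cells from non-lesional skin and day 2 and 50 genes set at each fold among 12038. Genes set 4-fold higher were found at a median ratio of 4.00, or 3.47 with the pseudocount, and 92% passed 2-fold by the rule. Genes set to 0.25 were found at 0.252, or 0.430 with the pseudocount, so log2 folds of lower genes are drawn towards 0, and 68% passed (56% in the day 7 pair). Of genes set at exactly 2-fold or 0.5, 0% passed in the day 2 pair, so counts of members by the rule leave out differences near 2-fold. Intervals held the true ratio in 95.3% of unchanged genes, and 3 of 100 unchanged lists fell outside the central 95% of random lists. Counts were drawn by the model that the intervals assume, so these figures check the calculation only. They do not show how intervals or percentiles hold where whole lists of genes differ.

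The alternatives were a mitochondrial limit of 20%, at least 500 genes per cell, doublets kept, clustering at resolution 0.5 and 2, each library clustered alone, a class given to each cell, TMM and median-of-ratios scaling, the mean of per-cell CPM, totals without abundant genes, a pseudocount of 1, no minimum or at least 50 UMIs per gene, no limit on levels in other classes, and cells thinned to 1000 UMIs. One more, without the clusters led by proliferation genes, was added after the data were seen. Gene folds were not described for Schwann or melanocyte-like cells, whose clusters differed in mixture between libraries, or for erythroid-like cells, which carried fibroblast RNA. Cebpd, Ighm, Trac, Trbc1, Trbc2 and Trdc were not in the gene table and were not used here. Not every gene that the rule named is reported here.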

Results

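Single-cell transcriptomes were measured in dorsal skin of male C57BL/6 mice aged 7 to 9 weeks. The 3 libraries were 1 each of non-lesional skin, wound bed at day 2 and wound bed at day 7 after a full-thickness wound of 1.0 cm by 0.5 cm, made in the resting phase of the hair cycle. Each value is a count of unique molecular identifiers (UMIs) per gene and cell. The non-lesional library held 123088680 UMIs over 10857 barcodes, the day 2 library 138046172 over 8707 and the day 7 library 102345327 over 7317. After filtering, 9390, 7362 and 4773 cells were kept, with medians of 9413.5, 7523.5 and 10978 UMIs per cell. There were no replicates, so differences between libraries are given as values without a test. Intervals are exact 95% counting intervals, and they cover counting error only. The title of the series concerns IL1 and WNT signalling in the dermal adipocyte lineage, and the comparisons follow that question: which cell types each skin held, and how genes of these pathways differed in fibroblast-like cells, where adipocyte progenitors of the dermis are found. Levels are given as CPM, the UMIs of a gene summed over the cells of a class in a library and scaled to the same total. Log2 folds carry a pseudocount of 5 CPM, and ratios of levels carry none.

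The first comparison asked which cells each skin held. Fibroblast-like cells were the largest class in all 3 libraries, at 69.1% of non-lesional cells (interval 68.1 to 70.0), 55.7% at day 2 (54.6 to 56.9) and 50.2% at day 7 (48.8 to 51.6). Neutrophil-like cells, the phagocytes that enter a wound early, made up 27.7% of cells at day 2 (26.7 to 28.7) and 3.65% at day 7 (3.13 to 4.22). Non-lesional skin held 6 of them, a share of 0.0639%. Monocyte- or macrophage-like cells were 0.788% of non-lesional cells, 5.05% at day 2 (4.56 to 5.58) and 6.85% at day 7 (6.15 to 7.60). Dendritic-like cells were 1.04%, 7.19% and 6.64%. T, NK or innate lymphoid-like cells were 4.60%, 2.42% and 13.9%.

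Keratinocyte-like cells, the cells of the epidermis and hair follicle, were 16.0% of non-lesional cells and 1.84% at day 7. At day 2 there were 0 of them, which allows a share of up to 0.0407%. Pericyte or smooth muscle-like cells were 3.24% of non-lesional cells, 0.177% at day 2 and 4.02% at day 7. Endothelial-like cells were 0.373%, 0.109% and 2.98%, and lymphatic endothelial-like cells 0.501%, 0.136% and 0.922%. Schwann or melanocyte-like cells were 2.01%, 0.0407% and 1.80%. Mast or basophil-like cells, at 0.415%, 0.448% and 0.566%, had overlapping shares. Skeletal muscle-like cells were 0.788% of non-lesional cells and 0.0272% at day 2, with 0 at day 7. Erythroid-like cells were 0.0107%, 0.964% and 1.59%. As clustered here, no cells of any library were named from the adipocyte marker list. Shares depend on the settings, and day 2 neutrophil-like cells held a median of 886.5 UMIs. With a clustering resolution of 2 their day 2 share was 12.01%. With at least 500 genes per cell the day 2 share of neutrophil-like cells was 8.43% and that of fibroblast-like cells 73.4%, above the non-lesional share. With a class given to each cell by itself the day 7 share of fibroblast-like cells was 70.1%, above day 2, and the shares of monocyte- or macrophage-like cells were 1.98% and 3.33%. Dendritic-like cells were then 0.0533%, 2.38% and 1.72%, and T, NK or innate lymphoid-like cells 3.15%, 1.13% and 5.78%. Skeletal muscle-like cells were 0.0639% of non-lesional cells in that setting, and at day 7 endothelial-like cells were 1.70%, Schwann or melanocyte-like cells 0.943% and erythroid-like cells 2.51%. With at least 500 genes there were 0 erythroid-like cells in any library, and mast or basophil-like cells were 0.260% of non-lesional cells. With each library clustered alone T, NK or innate lymphoid-like cells were 8.19% at day 7.

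**Figure D1:**
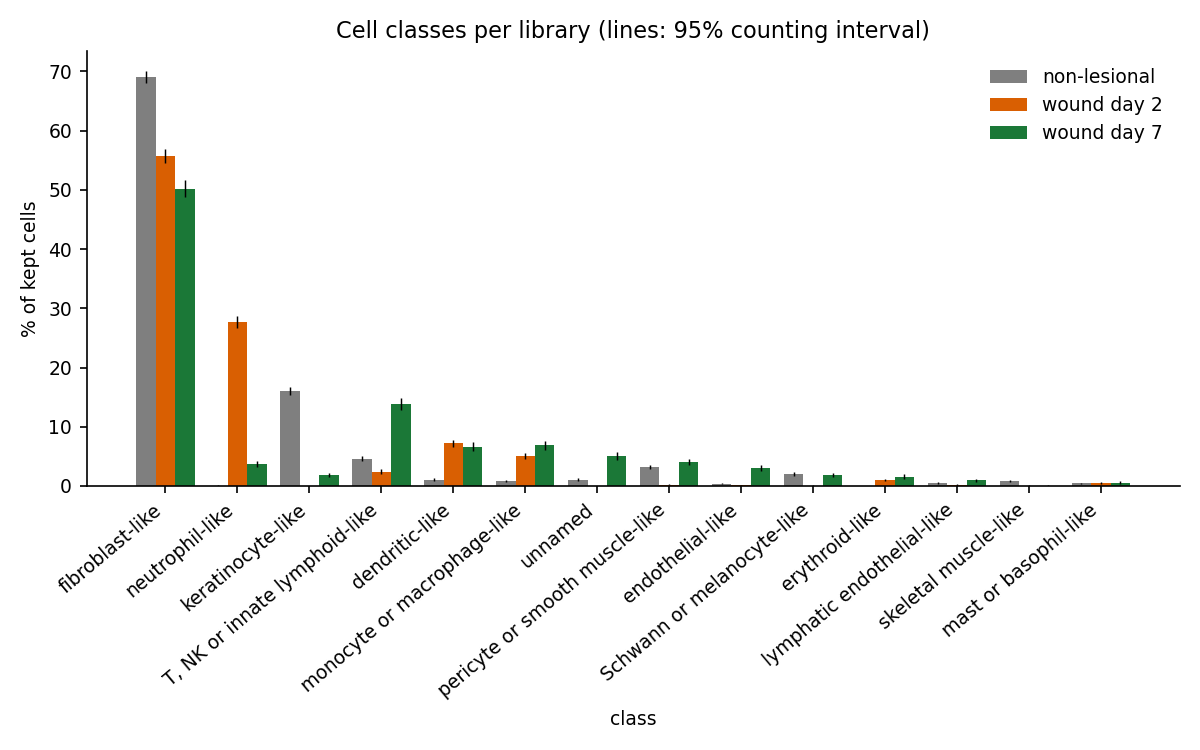
Bars give the percentage of kept cells in each class for the 3 libraries, and black lines give the 95% counting interval of each share. Neutrophil-like cells stood at 27.7% of the day 2 library against 3.65% at day 7, and keratinocyte-like cells at 16.0% of the non-lesional library against 0 at day 2.

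Fibroblast-like cells of each library fell in clusters of their own. The non-lesional ones lay mostly in clusters led by Smpd3 and Pi16 (1644 cells), Gal (1232), Myoc (1136), Igfbp2 and Grem1 (929), C6 and Tnmd (826) and Coch and Dkk2 (705). Those of day 2 lay in clusters led by Cxcl5 (1753), Hist1h2ap (1494) and Cxcl14 (844). Those of day 7 lay in clusters led by Prss35 and Ptn (1260), H19 and Mgp (550) and Hist1h2ae (300), and 185 shared the cluster led by Coch. The cluster led by Hist1h2ap, of dividing cells, held 36.4% of the fibroblast-like cells of day 2, and that led by Hist1h2ae 12.5% of those of day 7. The fibroblast-like cells numbered 6484, 4103 and 2397, with medians of 9294, 26093 and 26235 UMIs per cell.

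The comparison of day 2 with non-lesional skin asked how IL1 and WNT genes of fibroblast-like cells stood early after wounding. Some genes that IL1 and NF-kB induce were at far higher levels at day 2: of 31 measured members of that list 14 were at least 2-fold higher and 1 at least 2-fold lower. The neutrophil-attracting chemokine Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624) stood at 2637 CPM against 0.189. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) stood at 7100 CPM against 10.9, a ratio of 651 (604 to 702). The granulocyte growth factor Csf3 was at 155 CPM against 0.410 and Lcn2, which binds bacterial iron carriers, at 113 CPM against 0.772. The list's median log2 fold was 0.77, at percentile 98.48 of 10000 random lists matched for expression, and its lead genes were far above that median. Of 22 inflammatory macrophage genes 15 were at least 2-fold higher and 0 lower in these cells, with a median of 2.03. Free RNA at the share worked out from neutrophil and macrophage genes would bring a median of 30.03% of the level of those 15, and 178% for Il1b, 131% for Irg1 and 124% for Tnf, so that list was not read as expression by fibroblasts. The MHC class II median was 0.58, and 0.04 with a class per cell.

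The receptor for IL1 itself, Il1r1 (ENSMUSG00000026072, chromosome 1, 40225080 to 40317257), was 2.09-fold higher at day 2 (2.02 to 2.16), at 155 CPM against 74.2, a log2 fold of 1.01, or 0.63 with thinned cells. With cells thinned to 1000 UMIs, 12.7% of day 2 fibroblast-like cells had an Il1r1 UMI against 8.08% of non-lesional ones (83.7% and 43.4% unthinned). In day 2 neutrophil-like cells, median depth 886.5 UMIs against 26093, the share was 1.36% of the 809 cells deep enough to thin (1.77% of all unthinned). The alarmin Il33 was 16.5-fold higher (15.8 to 17.2) and its receptor Il1rl1 63.3-fold higher (56.2 to 71.5), while the decoy receptor Il1r2 had a log2 fold of -3.12. Of 18 members of the IL1 family list 6 were at least 2-fold higher and 3 lower, with a median of 0.52 at percentile 92.59. Il1b and Il1rn were among the 6, and free RNA would bring 178% and 74.96% of their level, against 0.0371% for Il1r1. Of 23 chemokines 11 were at least 2-fold higher and 2 lower, with a median of 0.89 at percentile 99.96. Cxcl3 had a log2 fold of 6.05 and Cxcl14, a chemokine of resting skin, 3.90. Free RNA would bring a median of 1.59% of the level of the 11 higher chemokines, but 131% for Ccl4 and 93.1% for Ccl3. Of 15 antimicrobial genes 7 were higher and 0 lower, with a median of 0.57 at percentile 99.98, or 1.99 with genes at 0 in 1 library placed at their bound and 3.09 with thinned cells. Of those 7, S100a8 and S100a9 served to set the share of free RNA and were not read as expression by fibroblasts. The chemokine median was 1.83 with a pseudocount of 1.

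WNT genes stood the other way. Of 20 measured targets of WNT signalling 8 were at least 2-fold lower at day 2 and 1 was higher, with a median of -0.71, below all 10000 random lists. It was -1.36 with a pseudocount of 1 and -1.21 with a class per cell. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback inhibitor that WNT signalling induces, was at 2.09 CPM against 27.3, a log2 fold of -2.19. The stem cell receptor Lgr5 had a log2 fold of -2.58 and the secreted antagonist Wif1 one of -2.24. The exception was Wisp1, a secreted WNT target, at 125 CPM against 23.3. The transcription factor Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356) was scarce in fibroblast-like cells, at 2.93 CPM in non-lesional skin and 0.0536 at day 2. Of 30 WNT ligands and receptors 0 were higher and 3 lower, with a median of -0.27 at percentile 0.03. The agonist Rspo1 had a log2 fold of -3.40, Wnt5a -1.42 and Wnt11 -1.12. Of 11 secreted antagonists 0 were higher and 4 lower, with a median of -0.35 at percentile 0.57. Dkk2 had a log2 fold of -1.48 and Sfrp2 0.50. These levels leave out an unnamed cluster of non-lesional skin led by Slc26a7, in which Lef1 stood at 330 CPM and Wif1 at 625.

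Genes of interstitial progenitors, the Dpp4- and Pi16-expressing cells that can give rise to preadipocytes, were far lower at day 2: 9 of 13 were at least 2-fold lower and 0 higher, with a median of -2.23, below all random lists. Pi16 (ENSMUSG00000024011, chromosome 17, 29317680 to 29330593) was at 223 CPM against 1099, and Dpp4 (ENSMUSG00000035000, chromosome 2, 62330073 to 62412231) at 26.1 against 208. With cells thinned, 16.4% of day 2 fibroblast-like cells had a Pi16 UMI against 35.5% of non-lesional ones (63.7% and 55.7% unthinned), and 6.80% of the day 2 neutrophil-like cells deep enough to thin did (8.28% unthinned). Of 18 committed preadipocyte genes 3 were higher and 7 lower, with a median of -0.36 at percentile 0.18. The basement membrane collagen Col15a1 and the lipid carrier Apoe had log2 folds of -3.43 and -3.02, against 2.10 for the fatty acid carrier Fabp4. With thinned cells the median of this list was -0.9999. Of 19 adipogenic transcription regulators 0 were higher and 5 lower, with a median of -0.51 at percentile 0.02, and Klf4 and Klf2 stood at -3.17 and -2.11. Of 14 mature adipocyte genes 1 was higher and 3 lower, with a median of -0.01 at percentile 21.29. Pparg, the master regulator of fat cells, was at 1.39 CPM against 0.857 at day 2, and Adipoq, an adipocyte hormone, was found in 1 non-lesional cell (0.0154%), at 0.363 CPM, and at 0.0179 at day 2. Dlk1 was at 0.363 and 0.268 CPM. The antimicrobial peptide gene Camp was at 0.126 CPM in non-lesional skin and 2.59 at day 2, and the fibroblast receptor Pdgfra at 162 and 178.

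Structural genes were split at day 2. Of 36 collagen and matrix genes 11 were at least 2-fold higher and 16 lower, with a median of -0.45 at percentile 0.06. The collagen cross-linking enzyme gene Plod2 was 47.7-fold higher (43.6 to 52.4), while the small proteoglycan Lum was 19.6-fold lower and elastin (Eln) 13.9-fold lower. Of 20 myofibroblast genes 12 were higher and 0 lower, with a median of 1.54, above all random lists. The protease inhibitor Timp1 was at 6024 CPM against 56.6 and the matrix glycoprotein Tnc at 746 against 10.2. Of 22 proteases and inhibitors 6 were higher and 4 lower, with a median of -0.06 at percentile 7.13. Of 26 TGF-beta and BMP genes 2 were higher and 11 lower, with a median of -0.67. The BMP antagonist Grem1 had a log2 fold of -4.25, and the activin subunit Inhba 3.16.

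All 26 proliferation genes were at least 2-fold higher at day 2, with a median of 3.04, and the histone gene Hist1h2ap had a log2 fold of 6.46. Of 28 hypoxia and glycolysis genes 19 were higher and 0 lower, with a median of 1.75, and the lactate exporter Slc16a3 and the cytokine Mif had log2 folds of 4.02 and 3.58. Of 23 oxidative phosphorylation genes 9 were higher and 0 lower, with a median of 0.95 at percentile 99.58. Of 21 immediate early and heat shock genes 6 were higher and 9 lower, with a median of -0.76 at percentile 0.13. Fosb had a log2 fold of -2.33, against 2.52 for the mitochondrial chaperone Hspd1. Of 24 interferon response genes 0 were higher and 7 lower, with a median of -0.05 at percentile 6.70. Other genes named as most higher were Serpinb2, the lubricant Prg4, the growth factor Ereg and the carbonic anhydrase Car4, with log2 folds of 7.21, 6.83, 6.26 and 5.49. Those most lower were Ctla2a at -6.52, the scavenger receptor Scara5 at -5.69, the microfibril gene Mfap4 at -5.47, Itgbl1 at -5.04 and C1qtnf3 at -4.84. Clec3b, Kazald1, Cdh4, Myoc, Tnmd, Igfbp5 and Smpd3 lay between -4.50 and -4.31.

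The comparison of day 7 with non-lesional skin asked which of these differences were present when the wound bed held new tissue. Myofibroblast genes, of contraction and new matrix, were higher: 17 of 20 were at least 2-fold higher and 0 lower, with a median of 3.51. Smooth muscle actin, Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), was 76.3-fold higher (71.9 to 80.9) at 1376 CPM. Tagln, an actin-binding protein, was 31.1-fold higher (29.6 to 32.7), the wound fibroblast marker Lrrc15 68.3-fold (63.0 to 74.0) and the secreted phosphoprotein Spp1 281-fold (246 to 324). Spp1 is given as a list member. The naming rule did not pick it for these cells but did for monocyte- or macrophage-like cells of day 7. The part of its level that free RNA brings was not worked out, so it was not read as expression by fibroblasts alone. Of 36 collagen and matrix genes 12 were higher and 9 lower, with a median of 0.46 at percentile 88.07. Col12a1 (ENSMUSG00000032332, chromosome 9, 79598991 to 79718831), which links collagen fibrils, was at 1283 CPM against 24.7, and the prolyl hydroxylase subunit P4ha3 at 60.4 against 0.615. The growth factor Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220) was at 463 CPM against 0.725. The imprinted RNA H19, the secreted protease Prss35 and the tenascin Tnn had log2 folds of 5.98, 5.61 and 4.80. The median of all genes was 0.12 in this pair and 0.00 with median-of-ratios scaling, under which the collagen median was 0.05 (0.14 with TMM).

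IL1 response genes at day 7 were mixed, 6 of 31 at least 2-fold higher and 7 lower, with a median of -0.14 at percentile 0.54, which was -0.39 with TMM and -0.48 with median-of-ratios scaling. Cxcl5 was still at 415 CPM and Saa3 at 792, with log2 folds of 6.34 and 5.65, and the collagenase Mmp13 had one of 4.06. Il1r1 had a ratio of 1.24 (1.20 to 1.29) whose direction depended on scaling, with log2 folds of 0.30 by CPM, -0.01 with TMM and -0.10 with median-of-ratios scaling, and with thinned cells 8.75% (7.64 to 9.97) had a UMI against 8.08% (7.42 to 8.77). Il1rl1 was 31.9-fold higher (28.2 to 36.1) and Il1r2 15.8-fold lower. Of 18 IL1 family genes 3 were higher and 4 lower, with a median of 0.28 at percentile 62.38, which was -0.07 with median-of-ratios scaling. Of 24 chemokines 10 were higher and 3 lower, with a median of 0.68 at percentile 99.95, or 0.79 with genes at 0 placed at their bound. Cxcl13, which attracts B cells, had a log2 fold of -4.02. Of 13 antimicrobial genes 3 were higher and 0 lower, with a median of 0.31, 1.08 with thinned cells and 0.07 with a class per cell. The part that free RNA brings was not worked out for day 7.

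WNT targets were again lower: 6 of 21 by at least 2-fold with 2 higher, and a median of -0.71, below all random lists. Axin2 was at 8.98 CPM, 3.04-fold under its non-lesional level, and Lef1 at 0.556. Wisp1 was 10.1-fold higher (9.54 to 10.6), and the transcription factors Prdm1 and Twist1 had log2 folds of 1.25 and -1.30. WNT ligands and receptors were split, 4 of 30 higher and 4 lower, with a median of 0.03 at percentile 3.25. Rspo1 and Wnt11 had log2 folds of -3.03 and -1.85, against 1.67 for Wnt9a and 1.38 for the receptor Fzd1. Wnt5a was at 89.9 CPM, a log2 fold of 0.31. Of 12 secreted antagonists 1 was higher and 2 lower, with a median of 0.01 at percentile 16.66. Dkk2 had a log2 fold of -2.31 and Sfrp2 one of 0.46. These levels leave out an unnamed cluster of day 7 led by Wif1, in which Lef1 stood at 444 CPM and Wif1 at 1711. In fibroblast-like cells of day 7 Wif1 stood at 5.15 CPM. The lists were not worked out with the unnamed clusters included.

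Progenitor and preadipocyte genes at day 7 were lower as groups, with exceptions at single genes. The mature adipocyte list had a median near 0. No cells were classed as adipocytes and its member Adipoq was almost absent, so that median does not describe fat cells. Of 13 interstitial progenitor genes 10 were at least 2-fold lower and 0 higher, with a median of -2.09, and Pi16 and Dpp4 stood at 114 and 23.3 CPM. Of 18 committed preadipocyte genes 8 were lower and 3 higher, with a median of -0.83, below all random lists. The early B-cell factor Ebf2 and Col15a1 had log2 folds of -1.89 and -2.18. Among the 3 higher were Fabp4, 47.2-fold higher (41.7 to 53.5), and Dlk1. The part of the Fabp4 level that free RNA of other classes brings was not worked out at either time. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), a membrane protein of preadipocytes that restrains fat cell formation, was at 31.0 CPM against 0.363. A Dlk1 UMI was found in 2.18% of day 7 fibroblast-like cells thinned to 1000 UMIs and 0.0787% of non-lesional ones (10.9% and 0.170% unthinned). In day 7 T, NK or innate lymphoid-like cells, median depth 2289 UMIs against 26235, the share was 0.337% (1.06% unthinned). Of 19 adipogenic regulators 0 were higher and 5 lower, with a median of -0.69, and Klf4 stood at -2.87. Of mature adipocyte genes 0 were higher and 2 lower, with a median of -0.02 at percentile 3.66. Pparg was at 1.38 CPM, Adipoq at 0.0146, Camp at 0.614 and Pdgfra at 184.

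All 26 proliferation genes were also at least 2-fold higher at day 7, with a median of 2.65. Of 28 hypoxia and glycolysis genes 12 were higher and 2 lower, with a median of 0.88, and of 23 oxidative phosphorylation genes 6 were higher and 0 lower, with a median of 0.64 (0.47 and 0.24 with median-of-ratios scaling). Of 22 proteases and inhibitors 9 were higher and 4 lower, with a median of 0.31, and of 25 TGF-beta and BMP genes 1 was higher and 8 lower, with a median of -0.40. Immediate early and heat shock genes had 5 higher and 5 lower, with a median of -0.39. Interferon response genes had 1 higher and 3 lower, with a median of -0.21. Of 23 genes of endothelial activation and sprouting 3 were higher and 7 lower in these cells, with a median of 0.18 at percentile 77.62. The genes most lower were Smpd3 at -4.56, Scara5 and Myoc at -4.29, the actin-severing protein Gsn at -4.24 and the collagen processing enhancer Pcolce2 at -4.17. Cyp2f2, Cadm3, Il1r2, Inmt, C7 and Aldh3a1 lay between -3.99 and -3.64.

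**Figure D2:**
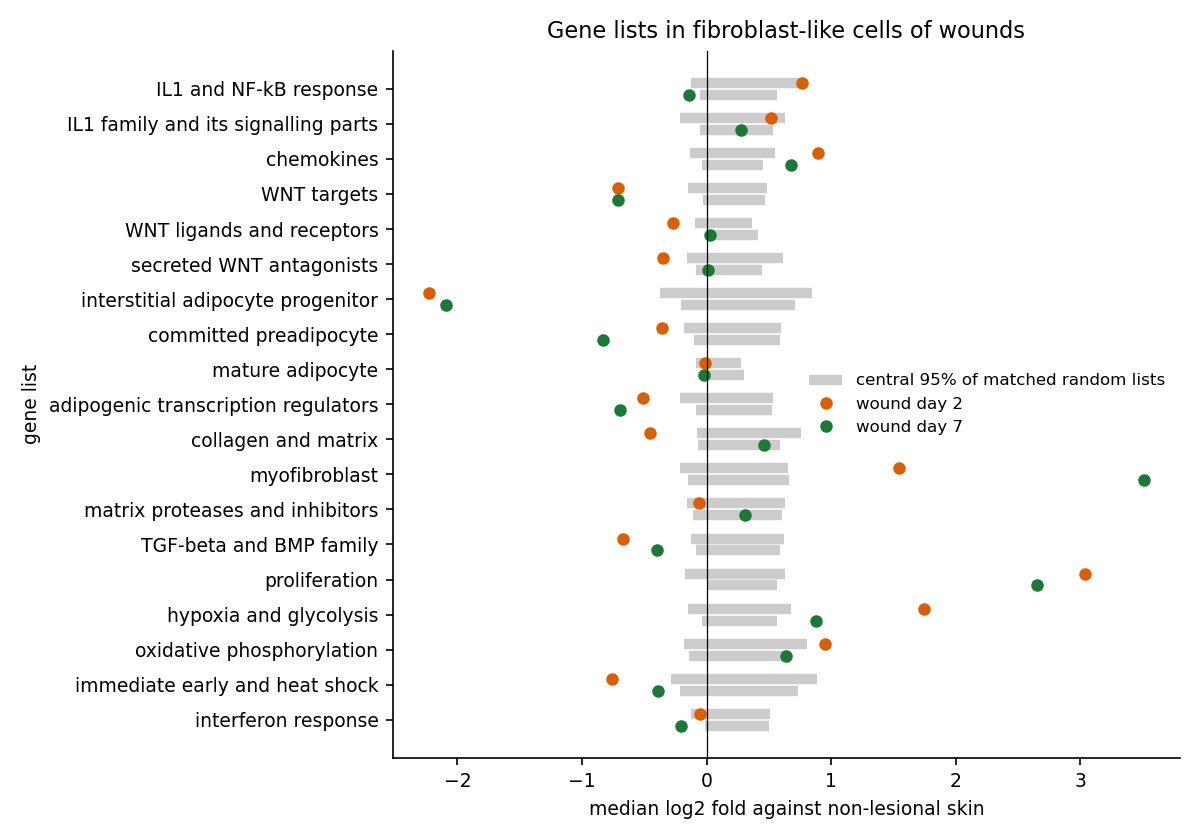
Points give the median log2 fold of 19 gene lists in fibroblast-like cells of day 2 and day 7 against non-lesional skin, and grey bars give the central 95% of matched random lists. The myofibroblast list stood at 1.54 and 3.51, and the interstitial progenitor list at -2.23 and -2.09.

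**Figure D3:**
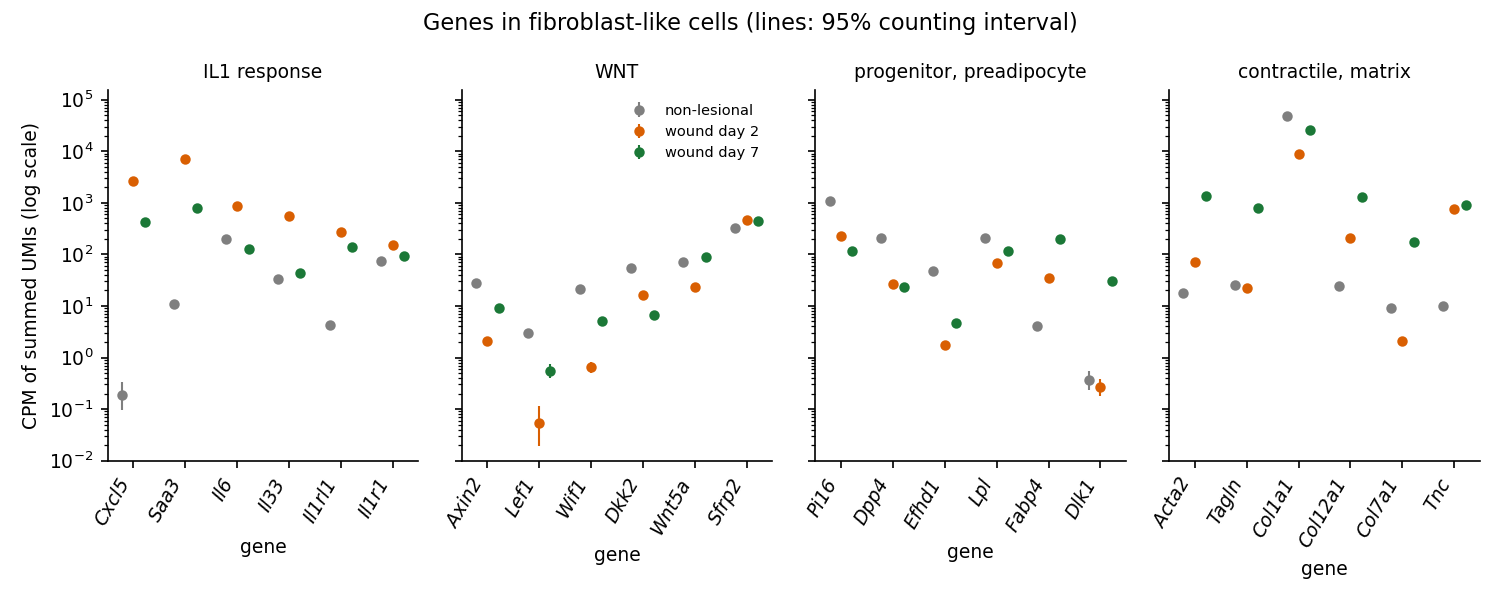
Points give CPM of summed UMIs on a log scale in fibroblast-like cells of the 3 libraries, with lines for the 95% counting interval. Saa3 stood at 10.9, 7100 and 792 CPM, and Acta2 at 18.1, 69.5 and 1376 CPM.

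The comparison of day 7 with day 2 asked how the wound fibroblast-like cells differed between the times. IL1 response genes were lower at day 7: 16 of 31 by at least 2-fold with 1 higher, and a median of -1.07, below all random lists. Lcn2 was 52.1-fold lower, Il33 12.7-fold, Csf3 11.4-fold and Saa3 8.97-fold. Il1r1 had a log2 fold of -0.72. Collagen and matrix genes were higher: 16 of 36 by at least 2-fold with 4 lower, and a median of 0.96, above all random lists. Lum was 10.3-fold higher (10.1 to 10.5) and the collagen VI genes Col6a1, Col6a2 and Col6a3 were 8.49-, 7.23- and 6.64-fold higher. Of 20 myofibroblast genes 12 were higher and 2 lower, with a median of 1.96, and Tagln and Acta2 were 35.7- and 19.8-fold higher.

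The medians of the WNT lists were above 0 for day 7 against day 2, by amounts that depended on the settings. Most members of these lists were not at least 2-fold higher or lower, so the medians do not describe WNT genes in general. Of 21 targets 3 were higher and 0 lower, with a median of 0.14 at percentile 96.87 (0.66 with thinned cells), and Lgr5 and Axin2 had log2 folds of 1.57 and 0.98. Of 30 ligands and receptors 4 were higher and 0 lower, with a median of 0.29 at percentile 99.99 (0.61 with thinned cells), and Wnt5a was 3.79-fold higher (3.62 to 3.97). Of 11 antagonists 1 was higher and 0 lower, with a median of 0.20, or 0.43 with a pseudocount of 1. Of 18 committed preadipocyte genes 4 were higher and 2 lower, with a median of 0.27 at percentile 98.82 (0.61 with thinned cells). Dlk1 and Fabp4 had log2 folds of 2.77 and 2.35. Interstitial progenitor genes had 1 higher and 2 lower, with a median of -0.13, which was 0.50 with thinned cells. Hypoxia and glycolysis genes were lower, 11 of 28 by at least 2-fold, with a median of -0.95, and proliferation genes had a median of -0.47 with 3 of 26 lower. The genes most higher were Ptn and Prss35 at log2 folds of 6.15 and 5.50, Mfap4 at 4.71, the anchoring fibril collagen Col7a1 at 4.65, Tnn at 4.61, C1qtnf3 at 4.47, Actg2 at 3.95, Aspn at 3.68, and Col11a1 and the cell cycle inhibitor Cdkn1c at 3.67. The genes most lower were Cxcl13 at -4.91, Serpinb2 at -4.84, Prg4 at -4.72, Cxcl14 at -4.39, Lmcd1 at -3.85, Car4 at -3.80, Thbd at -3.48 and Timp1 at -3.14.

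The next comparison asked which classes held IL1 ligands and receptors. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), the secreted cytokine, was at 14320 CPM in neutrophil-like cells of day 2 and 14860 at day 7. In monocyte- or macrophage-like cells Il1b stood at 1249 CPM in non-lesional skin, 12840 at day 2 and 3122 at day 7, and in dendritic-like cells at 1811, 6559 and 5269. Fibroblast-like cells held 0.363, 24.2 and 12.9 CPM of Il1b. The day 2 value was 0.169% of that in neutrophil-like cells, and the neutrophil genes S100a8, S100a9 and Retnlg stood there at 0.138%, 0.172% and 0.0962% of theirs, so expression by fibroblasts themselves was not measured by it. Of the 809 day 2 neutrophil-like cells deep enough to thin 98.6% had an Il1b UMI (97.0% of all unthinned), against 2.42% of day 2 fibroblast-like cells (33.8% unthinned) and 5.22% of the 115 of 178 T, NK or innate lymphoid-like cells deep enough to thin (9.55% of all unthinned, median depth 1174 UMIs). The antagonist Il1rn stood at 5444 CPM in day 2 neutrophil-like cells and 1978 in day 2 monocyte- or macrophage-like cells. Il1a stood at 596 and 811 CPM in the same classes. The decoy receptor Il1r2 was at 838 CPM in day 2 neutrophil-like cells. Il1r1 was highest outside the immune classes, at 155 CPM in day 2 fibroblast-like cells and 177 in day 7 pericyte or smooth muscle-like cells. Il33 was at 557 CPM in day 2 fibroblast-like cells, and Il1rl1 at 538 CPM in day 2 T, NK or innate lymphoid-like cells.

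**Figure D4:**
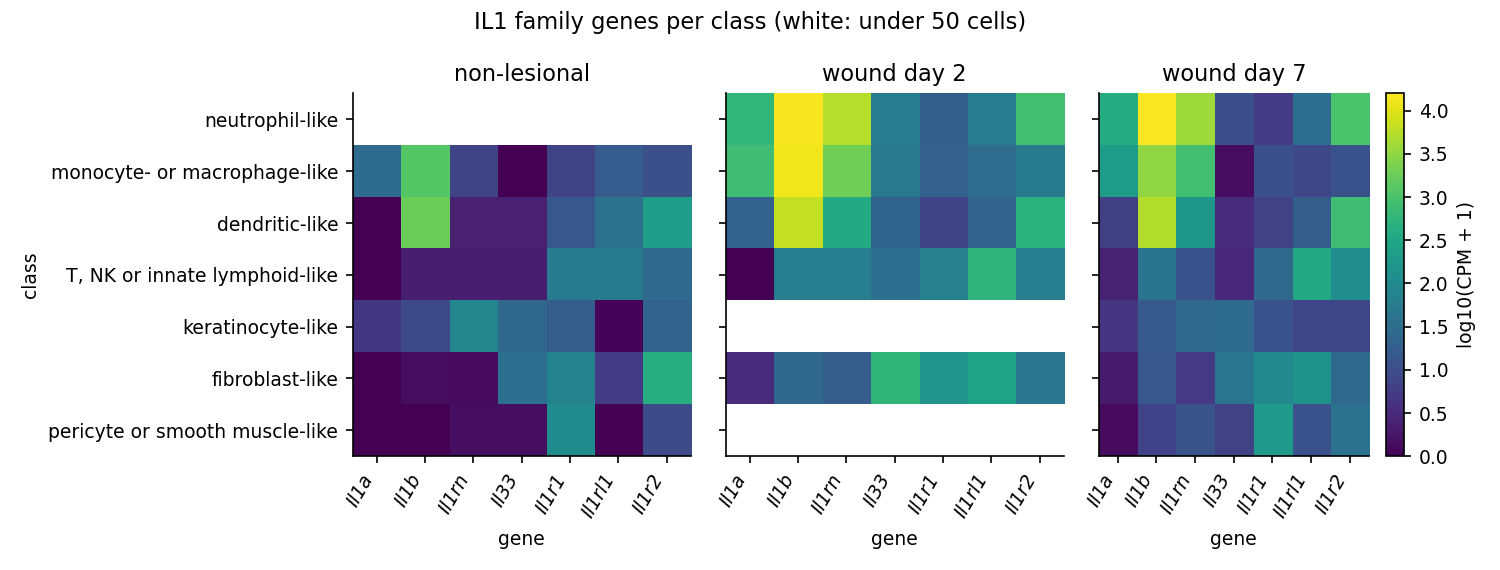
Colours give log10 of CPM plus 1 for 7 IL1 family genes in 7 classes of the 3 libraries, with classes under 50 cells left white. Il1b stood at 14320 CPM in neutrophil-like cells at day 2 and 14860 at day 7, and Il33 at 557 CPM in fibroblast-like cells at day 2.

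Of monocyte- or macrophage-like cells non-lesional skin held 74, of which 45 lay in a cluster led by Retnla that held 0 cells of day 2 and 2 of day 7. The other 29 shared a cluster with 372 cells of day 2 and 325 of day 7. At day 2, 21 of 23 inflammatory genes were at least 2-fold higher and 0 lower, with a median of 3.74. The chemokine Cxcl3 was at 6969 CPM against 6.28, a ratio of 1111 (307 to 9174) from 2 non-lesional UMIs. Arginase, Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), was at 2126 CPM with 0 non-lesional UMIs, at least 226-fold higher against a floor of 3 counts in that class. The activin subunit Inhba and the prostaglandin synthase Ptges were at least 68.3- and 48.7-fold higher. Il1rn stood at 1978 CPM against 6.28. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a product of resident macrophages, was at 13850 CPM in non-lesional skin and had 1 UMI at day 2, a log2 fold of -11.13. Among the other genes most lower, the lectin Cd209f was at 860 CPM against 0 at day 2, at least 245-fold lower, and Fcna, Cbr2, Ccl8 and Mgl2 had log2 folds between -6.71 and -6.46.

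At day 2, 6 of 7 antigen presentation genes of MHC class II were lower in these cells, with a median of -2.65. Of 13 complement genes 8 were lower and 2 higher, with a median of -1.29, and C1qa was 34.2-fold lower. With thinned cells that median lay further below 0. Of 31 IL1 response genes 27 were higher and 0 lower, with a median of 2.29. The part that free RNA of fibroblasts brings to these cells was not worked out. Of this list Saa3 stood at 674 CPM here against 7100 in day 2 fibroblast-like cells, Cxcl5 at 277 against 2637 and Il33 at 46.7 against 557. Other members stood higher here than in fibroblast-like cells, such as Cxcl2 and Cxcl1. The list was therefore not read as expression by macrophages alone. Of 24 repair-associated genes 12 were lower and 6 higher, with a median of -1.27. Of 19 chemokines 13 were higher and 4 lower, with a median of 3.38 (2.45 with genes at 0 at their bound). At day 7, 17 of 22 inflammatory genes were higher and 2 lower, with a median of 2.59, and all 8 MHC class II genes were lower, with a median of -2.91. Arg1 was at least 108-fold higher than in non-lesional skin and Spp1 43.0-fold (31.7 to 59.9). Retnla had 0 UMIs at day 7, at least 12810-fold lower. Against day 2, 17 of 23 inflammatory genes were lower at day 7 and 0 higher, with a median of -1.66. Phagolysosome and lipid handling genes were higher, 12 of 25 with 0 lower and a median of 0.81. The cathepsin Ctsk was 40.2-fold higher (26.2 to 65.0), the proton pump subunit Atp6v0d2 23.4-fold (11.3 to 58.5) and the lipase Lpl 7.99-fold (6.00 to 10.8). Oxidative phosphorylation genes were higher in 13 of 23, with a median of 1.12, and proliferation genes in 18, with a median of 1.27. With thinned cells the inflammatory median was -0.96, and that of proliferation genes 0.50. The median of all genes was -0.17 for day 2 against non-lesional skin and 0.10 with TMM. Collagen transcripts in these cells (median 2.07 at day 2) turned with doublets kept, to -0.60.

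Neutrophil-like cells of all libraries lay in 1 cluster. Against day 2, 6 of 17 granule and maturation genes were at least 2-fold lower at day 7 and 1 was higher, with a median of -0.88, or -0.50 with genes at 0 at their bound. Retnlg, made by circulating neutrophils, was 8.75-fold lower, and the granule gene Ngp was at 0 against 136 CPM, at least 9.90-fold lower. Hypoxia genes were lower in 9 of 28, with a median of -0.55, and Bnip3 and Ero1l had log2 folds of -2.48 and -2.10. Il1b had a ratio of 1.04 (1.00 to 1.08). The median of all genes was 0.00 and was -0.23 with TMM.

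Dendritic-like cells lay in clusters led by H2-Ab1 and by Ccl22. Folds were taken over these clusters together, so they do not tell a different mixture of the clusters from different levels within cells. Of 23 interferon response genes 17 were at least 2-fold higher at day 2 and 0 lower, with a median of 1.75, and at day 7 13 of 22 were higher, with a median of 1.18. Of 20 chemokines 18 were higher at day 2, with a median of 2.39. MHC class II genes were lower in 5 cases and higher in 1 at day 2, with a median of -1.31. The interferon-induced membrane gene Ifitm1 was 82.0-fold higher at day 2 (55.5 to 127) and the enzyme Il4i1 33.1-fold (18.4 to 66.5). The lysozyme Lyz2 was 53.3-fold lower. Cd207, the Langerhans cell lectin, was at 342 CPM in non-lesional skin, 0 at day 2 and 431 at day 7. Mfge8, which helps to clear dying cells, was 23.8-fold higher at day 7 than at day 2 (19.5 to 29.3). The median of all genes was 0.18 for day 2 and 0.02 with median-of-ratios scaling.

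T, NK or innate lymphoid-like cells of day 7 lay in clusters led by Cxcr6 (333 cells), Ctla4 and Foxp3 (279) and Cd3g (50), against 324, 36 and 72 in non-lesional skin and 133, 45 and 0 at day 2. The checkpoint receptor Ctla4 was at 47.7, 552 and 753 CPM. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), a transcription factor of regulatory T cells, was at 12.6, 150 and 323 CPM. With each library clustered alone the day 7 fold of Foxp3 turned to -1.03. The heat shock gene Hspa1b was 9.28-fold higher at day 2 (8.63 to 9.97). The chemokine Xcl1 was 22.6-fold lower at day 2, and the granzyme Gzma and the cytokine Il17f were 14.9- and 15.8-fold lower at day 7. Proliferation genes were higher in 10 of 26 at day 7, with a median of 0.82. The median of all genes was 0.22 at day 2 and -0.14 with TMM, and 0.32 and 0.02 at day 7.

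Keratinocyte-like cells were compared between day 7 (88 cells) and non-lesional skin (1505). Of 27 genes of activated keratinocytes 14 were at least 2-fold higher and 4 lower, with a median of 1.40, above all random lists. The wound keratins Krt6b, Krt6a and Krt16 were 111-fold (99.2 to 125), 64.9-fold (60.3 to 69.8) and 22.3-fold (21.5 to 23.2) higher. Of 20 basal and differentiation genes 5 were lower and 1 higher, with a median of -0.56, and the suprabasal keratin Krt77 was 26.3-fold lower. In pericyte or smooth muscle-like cells 31 of 36 collagen and matrix genes were higher at day 7 and 0 lower, with a median of 2.57. How much of this list free RNA of fibroblasts brings to these cells was not worked out. Col5a3 was 64.0-fold higher (46.1 to 91.5) and the matrix protein Postn 55.6-fold (43.3 to 72.6). Igfbp2 was 75.4-fold lower, and of 20 myofibroblast genes 8 were higher and 7 lower, with a median of 0.65, or 0.24 with thinned cells. These cells lay in different clusters: 227 of the 304 non-lesional ones in a cluster led by Sparcl1 and Myh11, and 162 of the 192 of day 7 in one led by Rgs5. Their median of all genes was 0.20 and was 0.01 with median-of-ratios scaling.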

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

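The tests of the IL1 response pattern, the tests of depth for the progenitor pattern, the tests without dividing clusters and the day 7 test of the cluster led by Coch were chosen after the result was seen.

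Of the genes named for fibroblast-like cells 4 were at least 2-fold to opposite sides of the non-lesional level at the wound times, and so, at any size, were the medians of 2 of the 4 lists compared for this (IL1 response, WNT targets, preadipocyte, collagen), which is what drew attention to them. Smaller differences of other genes, and other lists, were not considered. The differences between the times were not tested. The cell cycle inhibitor Cdkn1c had a log2 fold of -2.14 at day 2 and 1.53 at day 7, the collagen VI gene Col6a2 -1.26 and 1.57, the anchoring fibril gene Col7a1 -1.001 and 3.65, and the WNT modulator Dkk3 -1.33 and 1.19. The median of the IL1 and NF-kB response list was 0.77 at day 2 and -0.14 at day 7, and that of the collagen and matrix list -0.45 and 0.46. A pair of clusters outside the named classes drew attention because no comparison used them: one led by Wif1 held 5.05% of day 7 cells, and one led by Slc26a7 held 1.09% of non-lesional cells.

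The first pattern weighed was the higher level of IL1 response genes in fibroblast-like cells at day 2. Free RNA from neutrophils, monocytes or macrophages would bring a median of 0.452% of the level of the 14 higher members, and at most 10.2% (Cxcl2), which argues against it. With cells thinned to 1000 UMIs the median was 0.56. Levels are CPM of summed UMIs, in which thinning mostly changes the weight of each cell, so this decides nothing about depth. The value shows only that the difference stayed with cells of equal weight. Stress during digestion stays open: the immediate early and heat shock list had a median of -0.76, but 6 members were at least 2-fold higher and 9 lower, so it decides nothing. The time after wounding stays open as an untested biological difference, and with 1 library per group it may also be a difference between animals or preparations.

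The second pattern was the lower level of interstitial progenitor genes in fibroblast-like cells of both wounds. With thinned cells the medians were -2.40 at day 2 and -2.16 at day 7, so the difference stayed with cells of equal weight. As above, thinning decides nothing about depth. Without the non-lesional cluster richest in the list, led by Smpd3 and Pi16 with 1644 cells, the medians were -0.19 and -0.42, so most of the difference was against that cluster. Its leading genes include Pi16, Akr1c18, Efhd1, Anxa3 and Dpp4 of this same list. Absence of the cluster and lower levels of these genes therefore cannot be told apart. Fibroblast-like cells of day 2 lay almost wholly in clusters of their own, so every non-lesional cluster was nearly absent at that time. Against each other non-lesional cluster of at least 50 cells the medians lay between -1.44 and 0.65. Leaving out the richest cluster was likely from the start to move the median upwards, but how far was not fixed in advance. Whether its cells were lost, were not sampled in the wound bed or had taken on other expression was not tested.

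The third pattern was the lower level of WNT targets in fibroblast-like cells of both wounds. A higher share of dividing cells is argued against, since the medians without clusters led by proliferation genes were -0.80 at day 2 and -0.68 at day 7. At day 7 the non-lesional cluster richest in the list, led by Coch and Dkk2, was not absent. It held 7.72% of fibroblast-like cells there and 10.9% in non-lesional skin. Against non-lesional cells without it the median was -0.32, between the limits set for either reading. The day 7 cells of the cluster were kept in that comparison, so the median decides nothing. Only a bound on its share, set after its cells were seen, argued against absence. Fibroblast-like cells of day 2 lay almost wholly in clusters of their own, so every non-lesional cluster was nearly absent there. The cluster led by Coch held 0.0731% of them, and without its 705 non-lesional cells the median was -0.30 against -0.71. At day 2 its absence, which was not particular to it, and lower levels within cells cannot be told apart. This median lies between the limits set for either reading. The list was lower against this cluster (-1.59 and -1.02) and that led by Igfbp2 (-1.24 and -0.85), while against the other 4 the medians lay between -0.26 and 0.18, so which cells were present may matter at both times, and time after wounding is untested.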

How the results depend on the processing

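No paired analysis was possible because each group was 1 library from separate skin. Over 15 main results and 177 values under alternatives, 102 lay within the interval of the value as reported and 75 lay outside. Of the list medians among them 0 changed sign. The rest were shares of cells, which cannot change sign, but their order between libraries did change. With a class per cell the fibroblast-like share was 70.1% at day 7, above 61.5% at day 2. Of 137 gene results of at least 2-fold in fibroblast-like cells 0 of 1781 values changed sign, and in other classes 11 of 2903 did. For gene results under 2-fold 43 of 702 values changed sign in fibroblast-like cells and 52 of 463 in other classes. For list medians under 2-fold in fibroblast-like cells 45 of 1163 values changed sign. All alternatives were run, but with a class per cell dendritic-like cells of non-lesional skin were too few (0.0533% of cells) for gene values, as were erythroid-like cells with at least 500 genes. The cause was not tested for any value below. Medians in fibroblast-like cells against non-lesional skin are given as day 2 and day 7. With a class per cell, IL1 response was 0.92 at day 2, WNT targets -1.21 and -0.56, collagen -0.35 and 0.58, and preadipocyte -0.52 at day 7. Fibroblast-like shares were then 73.2%, 61.5% and 70.1% from non-lesional skin to day 7, monocyte or macrophage 1.98% and 3.33%, and neutrophil 26.1% and 3.00%. With TMM, IL1 response was 0.58 and -0.39, WNT targets -0.79 and -0.82, collagen -0.64 and 0.14, and preadipocyte -0.51 and -1.16. With median of ratios, IL1 response was 0.50 and -0.48, collagen -0.72 and 0.048, and preadipocyte -0.55 and -1.24. With the mean of per-cell CPM, IL1 response was 0.57 and -0.22, preadipocyte -0.30 and -0.91, and at day 7 WNT targets -0.57 and collagen 0.54. With totals without abundant genes, IL1 response was 0.92 at day 2, collagen -0.30 and 0.52, and preadipocyte -0.29 and -0.78. With cells thinned to 1000 UMIs, IL1 response was 0.56 and -0.18, collagen -0.48 and 0.59, and preadipocyte -0.9999 and -0.94. Without clusters led by proliferation genes, an alternative chosen after seeing the data, IL1 response was 1.10 and -0.048, collagen -0.34 and 0.58, WNT targets -0.80 at day 2 and preadipocyte -0.87 at day 7. With a pseudocount of 1, WNT targets were -1.36 and -1.09, and preadipocyte -0.57 at day 2. At day 2 WNT targets were -0.65 with no minimum and -0.77 with at least 50 UMIs. With doublets kept, collagen was -0.47 at day 2, fibroblast shares 67.2%, 58.0% and 48.8%, and the day 2 neutrophil share 25.9%. With each library alone, collagen was -0.47 and 0.45, preadipocyte -0.81 at day 7, fibroblast shares 63.2% (non-lesional) and 47.8% (day 7), and monocyte or macrophage 4.52% and 5.93%. With at least 500 genes, fibroblast shares were 73.4% and 52.5% and neutrophil 8.43% and 1.92%. The day 7 fibroblast share was 51.7% with a mitochondrial limit of 20%. At resolution 2, the day 2 monocyte or macrophage share was 4.43%, and neutrophil shares 12.01% and 2.05%. Values that turned with each library alone were, in T, NK or innate lymphoid-like cells, Ass1 at -0.38 (day 7 against non-lesional skin) and -0.42 (against day 2), Foxp3 at -1.03 and -4.36, and Ifi27l2a at -0.76 (against day 2). In dendritic-like cells at day 7 Epcam turned to -0.89 and Hpgds to -0.18. In monocyte- or macrophage-like cells Gpr183 turned at day 7 to -0.33, and to -0.34 with a class per cell and -0.84 with thinned cells. Slc9b2 against day 2 turned to -1.47 with a class per cell, and the collagen median at day 2 to -0.60 with doublets kept. Depth limits classes with few UMIs per cell: day 2 neutrophil-like cells held a median of 886.5.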

Other observations

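The tests of dermal papilla identity in this part were chosen after the result was seen. Of 3 genes chosen after their values were seen in day 7 fibroblast-like cells, H19 was at 331 CPM against 0.331 in non-lesional skin, Dlk1 at 31.0 against 0.363, and Cdkn1c, which halts the cell cycle, at 205 against 67.6. A cluster led by H19, Mgp and Dlk1 held 550 day 7 cells against 3 of non-lesional skin and 1 of day 2. Dlk1 was also found in pericyte or smooth muscle-like cells, at 140 CPM at day 7 against 2 UMIs in non-lesional skin, a ratio of 172 (47.2 to 1421).

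Erythroid-like cells of day 2 carried transcripts of fibroblasts, with Saa3 at 6018 CPM, Cxcl5 at 2147 and Dcn at 3114, so their profile was a mixture. In the day 7 library 25.2% of barcodes had over 10% mitochondrial UMIs, against 3.66% in non-lesional skin and 4.44% at day 2.

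A pair of clusters outside the named classes may hold cells of the dermal papilla, the signalling centre at the base of the hair follicle. It was examined with 20 papilla genes, but the list was written after the lead genes of these clusters, and the levels of many listed genes in them, had been seen. A high count was therefore likely from the start and decides nothing. In the cluster led by Wif1, 241 cells of day 7, 16 of the 20 were at least 4-fold above the fibroblast-like cells of that library with a pseudocount of 5 CPM on either side, and the most in any other class was 2, in endothelial-like cells. Corin stood at 456 CPM against 1.23, and Lef1 at 444, Alpl at 430, Rspo3 at 1369 and Ptch1 at 1144 CPM. Wif1, Rspo3, Corin, Ptch1 and Hhip were among the genes leading the cluster. Papilla and another origin cannot be told apart here, because genes chosen from the clusters keep it open. The cluster held cells of day 7 only and may be that library, not a type.

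In the cluster led by Slc26a7, 102 cells of non-lesional skin, 13 of the 20 papilla genes were at least 4-fold higher with the same pseudocount, and the most in any other class was 2, in Schwann or melanocyte-like cells. Crabp1 stood at 2327 CPM, Lef1 at 330, Wif1 at 625 and Notum at 264. Its origin stays open for the same reason, and it too may be that library, not a type.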
